A study of Arabidopsis thaliana with 6 samples.

How the data were processed

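Gene expression was measured by RNA-seq on the Illumina HiSeq platform in 6 libraries of whole Arabidopsis thaliana seedlings, 3 of wild type and 3 of the hy5-215 mutant, at 7 days of age and zeitgeber time 20 h. RNA was extracted with RNAiso Plus, per the labels' protocols. Groups and library numbers came from the sample titles. The authors deposited a table per library with FPKM (fragments scaled by gene length and by mapped fragments) for each gene, per the file headers. The submitters' processing notes name Trimmomatic 0.36, HISAT2 2.2.1.0, TopHat, Bowtie2, Cufflinks, DESeq 1.18.0 and the build TAIR10, without saying which step used which tool. Which annotation was used, how reads shared by similar genes were treated and whether strand was used are not given in the sources used here. FPKM divides by gene length and library size, so a change in a few abundant genes can shift all others, and read counts, which set the precision of low genes, cannot be read from it.

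The tables held 26984 genes, and all of them matched locus tags of nuclear protein-coding genes in the RefSeq TAIR10.1 annotation, which supplied symbols, product names and the coordinates printed. Organellar genes were not analysed here, nor were 460 further nuclear protein-coding genes of that annotation. Exact zeros are reported as listed at 0, and 4568 genes were at 0 in all 6 libraries. Relative depth was estimated from genes with values up to 0.15 FPKM, where values move in steps of a fragment. It was the most frequent ratio to wild type 1 among ratios close to equal depth, so larger differences could not be returned. No gene had an equal value above 0 in a pair of libraries, so no library was counted as a duplicate.

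The comparison had been planned before the data were examined for read counts, with a stated fallback for FPKM, and the fallback was used. Values were transformed to log2(FPKM + 1), genes with at least 1 FPKM in at least 3 libraries were kept, and hy5 was compared with wild type with limma 3.58.1 in R 4.3.3 (linear model with genotype as the only term, trended and robust empirical Bayes). Adjusted p-values are Benjamini-Hochberg values over 17205 genes, with a threshold of 0.05, and the size rule was a log2 fold change of 1. Gene lists, 25 in number with 383 distinct genes of which 7 were not in the tables, were fixed at the same point and were tested with camera (preset correlation 0.01, and estimated correlation) and fry, adjusted over the 25 lists. Each list also has a count of members past the threshold adjusted over the list alone. For 22 list members the fixed symbol differed from the reference, and these are printed under the reference symbol or locus tag.

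The genes named were set by a rule fixed beforehand. It takes 14 genes whatever their result (HY5, HYH, CHS, PIF4, PIF5, CCA1, LHY, TOC1, PRR7, COR27, COR28, BBX21, BBX22, ELIP2). It adds the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 FPKM, no overlap between genotypes and a symbol. From each list it takes up to 3 members with the smallest p among those past the threshold. Other members are named where they complete a small count, and these were chosen after their values were seen.

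The fit was tested on simulated data for hy5 versus wild type with 17205 genes and 200 changed genes in each of 5 runs. It recovered 20.8% of changes of 0.5 on the log2 scale, 63.6% of changes of 1, 92.8% of changes of 2 and 96.0% of changes of 3, and 3.94% of its calls were false. Over these runs 1 list was called. The simulated noise was drawn independently for each gene, so this does not test list calls where members vary together. The real fit called 3915 genes, far more than were planted, so these shares do not measure its recovery. Alternatives fixed beforehand were other pseudocounts (0.1 and 5), no filter or a filter at 5 FPKM, leaving out each library, and the estimated correlation. After seeing the data, 3 rescalings were added (median ratio, upper quartile and quantile). Tests in the closing section used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and blastn 2.17.0. Figures were drawn with matplotlib 3.10.9.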

Results

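RNA-seq profiles were compared between 3 libraries of wild-type Arabidopsis thaliana (accession Col-0) and 3 libraries of the hy5-215 mutant, which carries a lesion in HY5. HY5 encodes a basic leucine zipper transcription factor that promotes photomorphogenesis, the light-dependent programme of seedling development. RNA came from whole seedlings at 7 days of age that were grown in short days and harvested at zeitgeber time 20 h, in the dark part of the cycle. The wild-type libraries are numbered 1 to 3 and the hy5 libraries 4 to 6, and the comparison addresses which transcripts differ when HY5 is impaired. Expression values were FPKM for nuclear protein-coding genes. Their sums per library lay between 528554 and 556418, and between 16859 and 17123 genes reached 1 FPKM. Absolute read depth is unknown, but the spacing of the lowest values put the depth of the other 5 libraries at 0.938 to 1.03 times that of wild type 1. That estimate was searched only among ratios close to equal depth. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.991 to 0.996 between libraries of the same genotype and 0.980 to 0.986 between genotypes. The first principal component held 66.5% of the variance and separated the genotypes. The second held 14.2% and set wild type 3 (-24.7) apart from wild type 2 (16.7). The labels do not say that the libraries came from separate plantings, so p-values measure only the spread between these libraries, which may be technical.

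HY5 itself (AT5G11260) was measured first. In the RefSeq TAIR10.1 annotation it lies on the minus strand of chromosome 5 at 3593335 to 3595073, with 4 merged exons that span 1256 nt. Its level was 13.4 ± 0.45 FPKM (SD, n = 3) in wild type and 2.65 ± 0.66 FPKM (SD, n = 3) in hy5. All 3 hy5 libraries (1.88 to 3.04) lay below all 3 wild-type libraries (13 to 13.9). The difference was -2.00 on the log2 scale of FPKM + 1 (SE 0.14, limma adjusted p = 5.4e-07). Its closest homolog, HYH, another light-signalling bZIP factor, fell further, from 25.0 ± 1.56 to 2.69 ± 0.72 FPKM (log2 fold change -2.83, SE 0.14, limma adjusted p = 7.8e-09). Values below are given in the same way as mean FPKM ± SD with n = 3 per genotype, and log2 fold changes refer to FPKM + 1, hy5 over wild type, a scale that understates changes of low genes.

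Across the transcriptome, 3915 of 17205 tested genes (22.8%) passed a limma adjusted p of 0.05. Of these, 2010 were higher and 1905 lower in hy5. At least 2-fold changes were found for 381 genes, 209 of them higher and 172 lower. The total fell to 2201 without hy5 4 and to 2028 without hy5 6. The 2-fold count was 678 with a pseudocount of 0.1, 121 with a pseudocount of 5 and 240 among genes filtered at 5 FPKM.

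Among genes past the threshold with a reference symbol, a mean of at least 5 FPKM and no overlap between genotypes, the largest rises included OFP9, annotated as a transcription repressor, which was listed at 0, 0.0786 and 0 FPKM in wild type 1, 2 and 3 and at 22.5, 19.0 and 23.0 FPKM in hy5 4, 5 and 6. Other sequences at least 95% identical to OFP9 occur in the reference genome, so its reads are uncertain. SQN, a cyclophilin, rose from 5.21 ± 0.47 to 103.3 ± 23.6 FPKM (log2 fold change 4.05, SE 0.15, limma adjusted p = 3.4e-09). MRD1 rose from 3.81 ± 1.78 to 43.4 ± 1.05 FPKM, the early nodulin-like ENODL1 from 2.05 ± 0.85 to 25.7 ± 3.82 FPKM, and the sulfotransferase ST2A from 2.19 ± 0.11 to 22.7 ± 5.22 FPKM. The pectin methylesterase gene ATPMEPCRD rose 4.54-fold, the fatty acid reductase FAR1 (AT5G22500) 4.69-fold, EXL4 3.59-fold and FLP1 5.0-fold. Among the lower genes, the glycine-rich protein gene GRP9 fell from 49.6 ± 17.7 to 5.68 ± 0.63 FPKM, the lipid transfer protein gene LTP6 from 52.4 ± 4.88 to 10.9 ± 4.06 FPKM, and SDR1 from 16.6 ± 1.65 to 3.05 ± 0.17 FPKM (limma adjusted p = 3.6e-08 for SDR1). The defensin-like gene LCR67 stood at 12.9, 53.6 and 27.9 FPKM in wild type 1, 2 and 3 and at 0.322, 0.312 and 0 FPKM in hy5 4, 5 and 6, the same uneven order in wild type as the seed storage genes. Within these limits, the other genes with the largest falls were HYH, CHS, OLEO1, SESA1, SESA3 and SESA5, described with their groups.

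**Figure D1:**
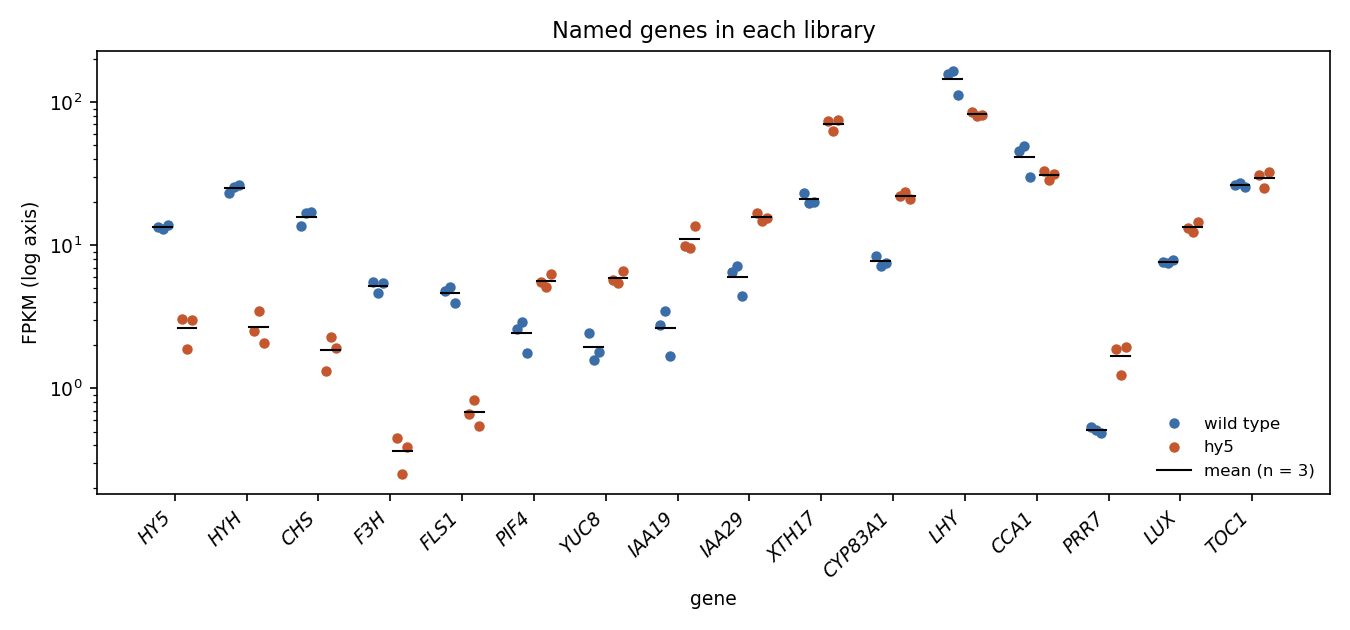
FPKM of 16 named genes on a log axis, with a point per library (blue, wild type 1 to 3; orange, hy5 4 to 6) and a bar at the mean of each genotype (n = 3). HY5, HYH, CHS, F3H and FLS1 lie lower in every hy5 library than in every wild-type library, PIF4, YUC8, IAA19, IAA29, XTH17 and CYP83A1 lie higher, and CCA1 and TOC1 overlap.

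Structural genes of flavonoid synthesis fell together. Of 13 tested members, 9 fell and the other 4 did not pass, with the same count adjusted over the list alone, and the median log2 fold change was -0.98. CHS, which encodes chalcone synthase, the entry enzyme of the pathway, fell from 15.8 ± 1.92 to 1.85 ± 0.49 FPKM (log2 fold change -2.57, SE 0.15, limma adjusted p = 5.6e-08). F3H, the flavanone 3-hydroxylase gene, fell from 5.22 ± 0.51 to 0.364 ± 0.10 FPKM, and the flavonol synthase gene FLS1 from 4.65 ± 0.61 to 0.680 ± 0.15 FPKM. The chalcone isomerase gene CHI did not pass, at 9.50 ± 1.29 against 9.01 ± 0.27 FPKM. The list passed the camera test with a preset correlation (adjusted p = 2.5e-07), with adjusted p = 0.19 with an estimated correlation. Upstream of this branch, 3 of 7 phenylpropanoid entry genes rose, also 3 adjusted over the list alone: PAL1 (42.9 ± 3.78 to 58.3 ± 3.31 FPKM), C4H (96.2 ± 4.50 to 120.9 ± 2.89 FPKM) and 4CL1 (41.6 ± 1.3 to 49.4 ± 1.81 FPKM). That list had a camera adjusted p of 0.065, which became 0.028 without wild type 3, 0.028 without hy5 6 and 0.037 with no filter on low values. The 4CL1 call was lost under every scaling, with no filter (limma adjusted p = 0.055) and without each library in turn (0.052 to 0.20), and the C4H call without hy5 4 (0.071). Of 8 tested flavonoid regulators, the repressor MYBL2 rose from 5.38 ± 0.35 to 11.9 ± 3.64 FPKM and the MYB-like gene AT1G70000 fell from 9.53 ± 0.81 to 7.11 ± 0.47 FPKM, the same 2 members adjusted over the list alone. The AT1G70000 call was lost without wild type 1 (0.058), hy5 4 (0.14), hy5 5 (0.067) or hy5 6 (0.066). The regulator list did not pass (camera adjusted p = 0.78).

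Light-signalling genes moved in both directions. Of 23 tested photoreceptor and light-signalling genes, 3 rose and 4 fell, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.29). The photoreceptor gene PHYA rose from 38.9 ± 3.03 to 56.2 ± 6.11 FPKM, and CRY2 and FHL also rose. HYH, RUP2, SPA3 and PHYB fell. RUP2, a repressor of the UV-B photoreceptor UVR8, fell from 10.8 ± 0.31 to 4.91 ± 0.48 FPKM (log2 fold change -1.0, SE 0.11, limma adjusted p = 5.1e-05). With CRY3 (10.4 ± 0.49 to 6.57 ± 0.45 FPKM), RUP2 made up the 2 of 6 tested UV-B and photoprotection genes that fell, 3 adjusted over the list alone. That list had a camera adjusted p of 0.065, which became 0.028 without hy5 6 and 0.0057 with no filter on low values. ELIP2, an early light-induced protein gene, was below the expression filter, at 0.824 ± 0.057 against 0.445 ± 0.10 FPKM. Among 14 tested B-box factors, 2 rose and 4 fell, or 2 and 7 adjusted over the list alone, with a camera adjusted p of 0.25 and a fry adjusted p of 0.013. BBX28 rose from 4.04 ± 0.26 to 7.59 ± 0.63 FPKM and BBX21 from 67.0 ± 4.54 to 87.3 ± 4.82 FPKM, the latter call being lost without hy5 6 (limma adjusted p = 0.053). BBX32 fell from 2.79 ± 0.083 to 1.1 ± 0.047 FPKM and BBX25 from 78.1 ± 5.92 to 57.1 ± 2.65 FPKM, and BBX4 and BBX18 fell too. BBX22 did not pass, at 2.76 ± 0.13 against 3.3 ± 0.81 FPKM. Here and below, members named outside the fixed rule for named genes were chosen after their values were seen.

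Auxin-responsive transcripts were higher in hy5. Of 28 tested genes of auxin response and transport, 20 rose and 8 did not pass, with 22 rising adjusted over the list alone and a median log2 fold change of 0.55. IAA19, an early auxin-induced gene, rose from 2.65 ± 0.90 to 11.1 ± 2.28 FPKM (log2 fold change 1.74, SE 0.19, limma adjusted p = 5.5e-05). SAUR22, a small auxin-up RNA linked to cell elongation, rose from 4.67 ± 1.02 to 14.9 ± 1.80 FPKM, and IAA29 from 6.04 ± 1.46 to 15.7 ± 1.01 FPKM. The SAUR19 to SAUR24 genes are close paralogs, so the division of reads among them is uncertain. The camera adjusted p was 2.5e-08, and adjusted p = 0.28 with an estimated correlation. Phytochrome-interacting factors (PIFs) and shade-induced genes, a list that shares IAA19 and IAA29, rose in 12 of 21 cases and fell in 1, or 14 and 1 adjusted over the list alone, with a median of 0.44. PIF4 rose from 2.44 ± 0.61 to 5.62 ± 0.60 FPKM (log2 fold change 0.96, SE 0.15, limma adjusted p = 0.00072). YUC8, an auxin biosynthesis gene, rose from 1.94 ± 0.45 to 5.94 ± 0.57 FPKM. PIF5 rose from 14.2 ± 2.73 to 18.7 ± 1.46 FPKM (limma adjusted p = 0.044), a call lost without wild type 3 (0.087), hy5 4 (0.072), hy5 5 (0.084) or hy5 6 (0.17) and with no filter on low values (0.084). The member that fell was UNE10, also known as PIF8. The PIF list had a camera adjusted p of 9.7e-07, and adjusted p = 0.28 with an estimated correlation.

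Cell wall remodelling genes changed strongly but not uniformly. Of 20 tested expansin and xyloglucan endotransglucosylase/hydrolase (XTH) genes, 11 rose and 4 fell, also adjusted over the list alone, with a median of 0.29. XTH17 rose from 21.0 ± 1.96 to 70.7 ± 6.48 FPKM (log2 fold change 1.70, SE 0.099, limma adjusted p = 5.8e-08), XTH24 from 192.3 ± 6.72 to 558.7 ± 87.0 FPKM, and XTH18 from 30.8 ± 2.28 to 71.6 ± 4.55 FPKM. The 4 that fell were EXPA1, EXPA10, XTH5 and XTH9. The camera adjusted p was 0.00039, and adjusted p = 0.19 with an estimated correlation. Of 13 tested gibberellin and brassinosteroid metabolism genes, 4 rose and 9 did not pass, also adjusted over the list alone. All 4 belong to brassinosteroid metabolism: BR6OX2 (6.35 ± 1.36 to 12.4 ± 1.35 FPKM), ROT3 (8.34 ± 1.2 to 12.7 ± 1.57 FPKM) and DWF4 act in synthesis and SOB7 (6.19 ± 1.04 to 10.7 ± 0.99 FPKM) in inactivation. The ROT3 call was lost without hy5 6 (limma adjusted p = 0.052). The list had a camera adjusted p of 0.020, with adjusted p = 0.28 with an estimated correlation and 0.086 with no filter on low values.

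**Figure D2:**
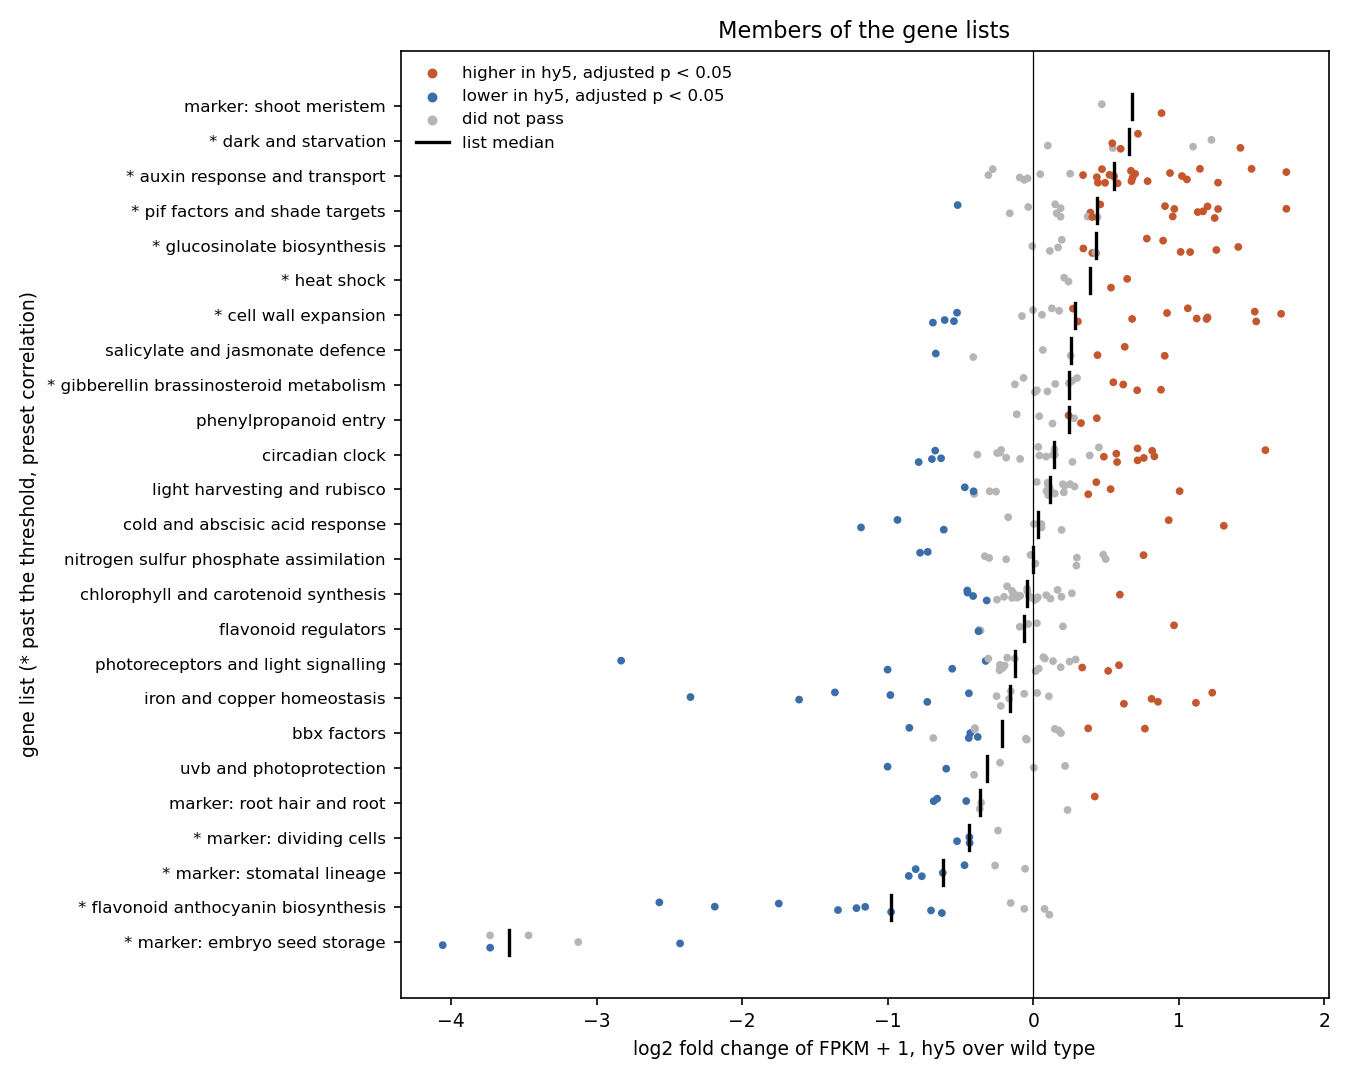
Log2 fold change of FPKM + 1 (hy5 over wild type, n = 3 each) for the tested members of 25 gene lists, with a point per gene coloured by whether it was higher (orange) or lower (blue) at a limma adjusted p of 0.05 or did not pass (grey), and a black bar at the list median. Stars mark the 11 lists past the camera threshold with a preset correlation, from embryo seed storage (median -3.60) to dark and starvation (median 0.66), of which 0 passed with an estimated correlation.

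Clock genes split by direction. Of 28 tested, 9 rose and 4 fell, or 11 and 5 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.16). LHY, a morning-phased repressor of the clock, fell from 145.2 ± 28.8 to 82.6 ± 3.08 FPKM (log2 fold change -0.79, SE 0.13, limma adjusted p = 0.00099). Its partner CCA1 did not pass, at 41.6 ± 10.1 against 31.1 ± 2.21 FPKM (limma adjusted p = 0.10), and passed without wild type 3 (0.0019). RVE8, LNK2 and ELF4 also fell. The evening complex gene LUX rose from 7.71 ± 0.20 to 13.3 ± 1.1 FPKM, PRR7 from 0.514 ± 0.028 to 1.69 ± 0.38 FPKM, and AT4G33980, known as COR28, from 2.76 ± 0.55 to 5.19 ± 0.95 FPKM. The Dof factor genes AT1G69570, known as CDF5, and CDF3 rose 3.64-fold and 1.96-fold. TOC1 (26.5 ± 0.87 against 29.6 ± 3.83 FPKM) and COR27 (34.5 ± 5.04 against 37.9 ± 4.01 FPKM) did not pass.

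Most photosynthetic genes did not pass. Of 22 tested light-harvesting and Rubisco small subunit genes, 4 rose and 2 fell, or 6 and 3 adjusted over the list alone. LHCB1.4 rose from 704.3 ± 77.9 to 1415 ± 144.2 FPKM (log2 fold change 1.01, SE 0.10, limma adjusted p = 2.1e-05), LHCB2.3 from 85.6 ± 7.13 to 124.0 ± 6.59 FPKM and LHCA4 from 980.8 ± 46.6 to 1274 ± 44.7 FPKM, and LHCB1.5 also rose. RBCS1B and RBCS2B fell. Both gene families hold near-identical copies, so single members are uncertain. The list had a camera adjusted p of 0.076, which became 0.015 without wild type 3, 0.037 without hy5 4, 0.028 without hy5 6 and 0.041 with quantile normalization. Of 25 tested chlorophyll and carotenoid synthesis genes, 1 rose and 4 fell, also adjusted over the list alone, with a camera adjusted p of 0.29 that became 0.044 without wild type 3. PORB, which encodes a protochlorophyllide oxidoreductase, rose from 442.1 ± 10.1 to 668.9 ± 37.9 FPKM. The chloroplast development factors GLK1 (19.2 ± 1.08 to 13.8 ± 1.5 FPKM) and GLK2 (92.4 ± 6.39 to 69.1 ± 2.81 FPKM) fell, as did CHLG and CHLH.

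Glucosinolate synthesis genes were higher in hy5. These genes make sulfur-containing defence compounds. Of 14 tested, 9 rose and 5 did not pass, also adjusted over the list alone, with a median of 0.43. CYP83A1 rose from 7.74 ± 0.64 to 22.2 ± 1.2 FPKM (log2 fold change 1.41, SE 0.10, limma adjusted p = 7.3e-07), CYP79F2 from 3.25 ± 1.05 to 8.95 ± 0.50 FPKM and MAM1 from 7.07 ± 0.88 to 13.9 ± 0.33 FPKM, all of the methionine-derived branch. The camera adjusted p was 6.1e-07, and adjusted p = 0.19 with an estimated correlation. Of 7 tested salicylate and jasmonate defence genes, AOS, VSP2 and WRKY33 rose and VSP1 fell, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.25). AOS, a jasmonate synthesis gene, went from 35.1 ± 2.08 to 47.9 ± 1.12 FPKM.

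Nutrient genes moved in both directions, and neither list of them passed by camera, while fry called the iron and copper list (adjusted p = 0.034). Of 18 tested iron and copper genes, 5 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.25). The iron-deficiency-induced peptide genes AT1G47395, AT2G30766 and AT1G47400 fell, AT1G47395 from 20 ± 3.01 to 5.85 ± 0.54 FPKM (log2 fold change -1.61, SE 0.12, limma adjusted p = 1.1e-06) and AT2G30766 from 23.7 ± 6.56 to 3.85 ± 1.33 FPKM. The other members that fell were bHLH38, bHLH101 and BTS. The genes that rose were COPT2, a copper transporter (7.82 ± 1.71 to 17.9 ± 1.46 FPKM), FSD1, FER1, FRO2 and IRT1, the last being the root iron transporter. Of 12 tested nitrogen, sulfur and phosphate genes, AMT1;2 rose and APR2 and NIA2 fell, or 3 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.88). APR2, which reduces activated sulfate, fell from 77.3 ± 6.37 to 44.9 ± 6.61 FPKM, the nitrate reductase gene NIA2 from 919.7 ± 165.7 to 558.0 ± 115.7 FPKM, and the ammonium transporter gene AMT1;2 rose from 15.2 ± 3.71 to 26.0 ± 2.36 FPKM.

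The dark and starvation, heat shock, and salicylate and jasmonate defence lists had been fixed beforehand as signs of handling. Dark and starvation genes and heat shock genes were higher in hy5 with the preset correlation (camera adjusted p = 0.28 for both with an estimated correlation). The defence list, described above, did not pass (camera adjusted p = 0.25). Cold and abscisic acid genes, which had not been named as such signs, had no common direction. Of 8 tested dark and starvation genes, 4 rose, or 7 adjusted over the list alone, with a median of 0.66: GDH2 (47.6 ± 3.3 to 70.0 ± 8.78 FPKM), IVD (17.5 ± 1.42 to 27.3 ± 4.94 FPKM), MCCA (19.9 ± 0.96 to 34.4 ± 9.28 FPKM) and ASN1, a glutamine-dependent asparagine synthetase gene. The hy5 libraries differed among themselves: MCCA stood at 38.9, 23.7 and 40.5 FPKM in hy5 4, 5 and 6. Its call was lost without wild type 1 (limma adjusted p = 0.057). The camera adjusted p was 0.00014, and adjusted p = 0.28 with an estimated correlation. Of 4 tested heat shock genes, HSP70 (8.76 ± 0.12 to 14.3 ± 0.92 FPKM) and HSP90.1 (3.02 ± 0.66 to 4.77 ± 0.12 FPKM) rose, also adjusted over the list alone. The HSP90.1 call was lost without hy5 4 (limma adjusted p = 0.062) or hy5 6 (0.064). That list had a camera adjusted p of 0.030, with adjusted p = 0.28 with an estimated correlation, 0.066 with no filter and 0.11 with a filter at 5 FPKM. Of 10 tested cold and abscisic acid genes, COR47 and RD29A rose and EM6, KIN1 and RAB18 fell, the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.86), its median being above 0 and its mean below. COR47 rose from 46.3 ± 4.90 to 116.3 ± 13.3 FPKM and RD29A from 3.68 ± 0.87 to 7.81 ± 0.24 FPKM. EM6, a late embryogenesis gene, fell from 3.52 ± 1.59 to 1.31 ± 0.43 FPKM, in the same libraries in which the seed storage markers were lower.

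Among markers of organs and cell types, the seed storage, stomatal lineage and dividing-cell lists were lower in hy5 with the preset correlation, while the root and shoot meristem lists did not pass by camera. The same 3 did not pass with an estimated correlation (adjusted p = 0.28 for seed storage, 0.23 for stomatal lineage and 0.28 for dividing cells). Of 6 tested embryo seed storage genes, 3 fell, or 6 adjusted over the list alone, with a median of -3.60. SESA1, SESA3 and OLEO1, which encode seed albumins and an oil body protein, passed, but their wild-type values were uneven: SESA3 stood at 5.24, 40.9 and 18 FPKM in wild type 1, 2 and 3 and at 0.0416, 0.0408 and 0 FPKM in hy5 4, 5 and 6. SESA1 stood at 5.77, 30.9 and 13.3 FPKM and at 0.261, 0.0422 and 0 FPKM. SESA5, outside the list, stood at 7.07, 71.7 and 12.6 FPKM and at 0.228, 0 and 0 FPKM. These calls were fragile: without hy5 4 the limma adjusted p was 0.075 for SESA1, 0.11 for SESA3, 0.14 for SESA5 and 0.051 for OLEO1, and without hy5 6 it was 0.084, 0.12, 0.15 and 0.19. Without hy5 5 it was 0.075 for SESA3, 0.11 for SESA5 and 0.093 for OLEO1. When a wild-type library was left out, SESA1, SESA3 and SESA5 fell below the expression filter and had no result. With a pseudocount of 5 the calls of SESA1 (0.062), SESA3 (0.080), SESA5 (0.12) and OLEO1 (0.084) were lost too, as was that of OLEO1 with a pseudocount of 0.1 (0.070). The seed list had a camera adjusted p of 1.1e-06, and adjusted p = 0.28 with an estimated correlation.

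**Figure D3:**
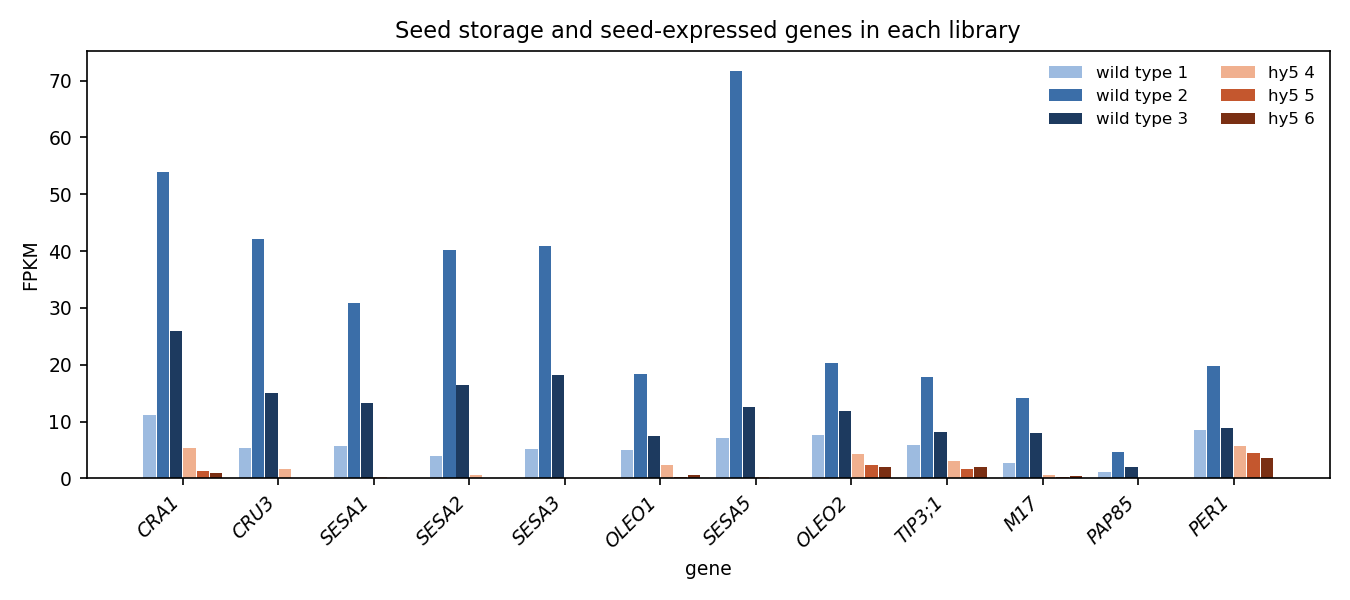
FPKM of 12 of the 21 seed storage and seed-expressed genes examined, chosen after their values were seen, on a linear axis from 0, with a bar per library (blues, wild type 1 to 3; oranges, hy5 4 to 6). Wild type 2 is the tallest bar for every gene shown, with SESA5 at 71.7 FPKM there against 7.07 FPKM in wild type 1, while AT3G01570, not shown, was highest in wild type 3 (3.93 FPKM against 2.78 FPKM in wild type 2).

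Of 7 tested stomatal lineage genes, 5 fell, also adjusted over the list alone, with a median of -0.62. SPCH, the factor that starts the lineage, fell from 2.65 ± 0.22 to 1.15 ± 0.065 FPKM, the receptor-like gene TMM from 11.3 ± 0.089 to 7.07 ± 1.09 FPKM, and TGG2, a myrosinase gene of guard and myrosin cells, from 28.5 ± 2.71 to 15.9 ± 2.47 FPKM. EPF1 and EPFL9 also fell. The camera adjusted p was 0.00039, and adjusted p = 0.23 with an estimated correlation. Of 4 dividing-cell markers, CYCB1;1, CYCB1;2 and CDKB1;1 fell, and all 4 did so adjusted over the list alone. CYCB1;2 went from 7.59 ± 0.49 to 4.98 ± 0.39 FPKM. The CDKB1;1 call was lost without wild type 1 (0.066), wild type 2 (0.089), hy5 4 (0.083) or hy5 6 (0.14), and the CYCB1;1 call without wild type 1 (0.096), wild type 2 (0.12), hy5 4 (0.17) or hy5 6 (0.15) and with no filter (0.051). This list had a camera adjusted p of 0.021, with adjusted p = 0.28 with an estimated correlation and 0.054 with a filter at 5 FPKM. Of 7 tested root markers, PYK10 rose (1500 ± 107.0 to 2009 ± 70.7 FPKM) and PRP3, LRX1 and EXPA18 fell, also adjusted over the list alone. The LRX1 call was lost without hy5 4 (0.055) or hy5 5 (0.057). The root list did not pass (camera adjusted p = 0.21, or 0.042 without wild type 2). Of 2 tested shoot meristem markers, STM rose from 3.18 ± 0.49 to 6.71 ± 1.09 FPKM, and both passed adjusted over the list alone. That list had a camera adjusted p of 0.051, which became 0.023 without wild type 2, 0.037 without hy5 4, 0.035 without hy5 5, 0.043 without hy5 6, 0.049 with median-ratio scaling and 0.045 with upper-quartile scaling.

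In total, 11 of the 25 lists passed the camera test with a preset correlation of 0.01, 7 higher and 4 lower in hy5. With an estimated correlation 0 passed by camera (4 at an unadjusted p of 0.05), and fry, which asks whether the members of a list move on balance in a common direction, called 16, the 11 included. The others called by fry were the shoot meristem, UV-B and photoprotection and B-box lists (fry adjusted p = 0.013 each), phenylpropanoid entry (0.022) and iron and copper (0.034). A regrouping that set wild type 1, wild type 3 and hy5 5 against the remaining libraries also gave 11 lists, while it gave 0 genes past the threshold. Its sides hold unequal numbers of each genotype, so part of the genotype difference remains in that contrast.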

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

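The 3 rescalings (median ratio, upper quartile, quantile) were chosen after seeing the data, and the other alternatives beforehand. The count of genes past the threshold stayed between 3038 and 4230 under the pseudocounts, filters and rescalings, and ranged from 2028 to 4309 when each library was left out, with the lowest counts without hy5 6 (2028) and without hy5 4 (2201). Of the 3915 calls, 51.3% were kept without hy5 6 and 55.4% without hy5 4, and in none of the 13 fits was a shared call opposite in direction. The share of higher genes lay between 46.9% and 55.8%, and the median log2 fold change moved to at most -0.018 under a rescaling. The 2-fold count became 678 with a pseudocount of 0.1, 121 with a pseudocount of 5 and 240 with a filter at 5 FPKM. The pseudocount shrinks the fold of low genes by construction, and the stricter filter tested 11770 genes. The HY5 difference passed in all 13 fits (-2.33 to -1.27).

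List calls depended on the correlation assumed: 11 with the preset value and 0 with an estimated correlation. Without single libraries 11 to 15 lists passed. Directions turned only in lists that had not passed. With a filter at 5 FPKM, the flavonoid regulators (adjusted p = 0.90) and the clock list (adjusted p = 0.93) turned. Without single libraries, the adjusted p ranged from 0.62 to 0.95 for the flavonoid regulators, from 0.62 to 0.97 for the cold and abscisic acid list and from 0.54 to 0.95 for the nitrogen, sulfur and phosphate list, with direction turned without hy5 4 for the flavonoid regulators, without wild type 1 for the cold and abscisic acid list and without wild type 3, hy5 4 or hy5 6 for the nitrogen, sulfur and phosphate list. The cause was not tested. For single genes named by the fixed rule, 1092 results were the same, 52 lost their call and 1 gained it (CCA1 without wild type 3). A gene below the expression filter in a fit had no result there. SESA1, SESA3 and SESA5 had results in 10 of the 13 fits. Calls of members named outside that rule were not followed under the alternatives. For lists, 311 were the same, 15 lost their call, 17 gained it and 7 turned.

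No paired analysis was possible because the labels number the libraries 1 to 3 and 4 to 6, so the genotypes share no number. The planned count-based tests and scalings were not run, since the values are FPKM, nor was the fit without organellar genes, since none entered the tests. Without read counts, how far low genes are limited by depth cannot be stated. In simulated data over 17205 genes, 20.8% of changes of 0.5 on the log2 scale were recovered. That simulation planted 200 changed genes per run, while the real fit called 3915, so the share does not measure recovery here. Genes of small change that did not pass are not shown to be unchanged.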

Other observations

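Apart from the regroupings for all genes past the threshold and for lists, and the search for near-identical copies, all of the tests below were chosen after the result was seen. Product families were tested beside the fixed lists, with which some overlap, taking 169 families of at least 10 tested genes and a one-sided Fisher exact test in each direction, adjusted over 338 tests and treating genes as independent. Peroxidases, which act on cell wall phenolics and hydrogen peroxide, rose in 21 of 46 cases (45.7%, against 11.7% of all tested genes, Fisher exact adjusted p = 3.0e-06). PRXR1 went from 389.7 ± 26.0 to 815.4 ± 31.8 FPKM (SD, n = 3) and AT2G41480 from 4.76 ± 0.81 to 21.9 ± 1.85 FPKM, while 6 peroxidase genes fell. Berberine bridge enzyme-like oxidases rose in 9 of 15 cases (adjusted p = 0.00087). Dirigent-like proteins, known for lignan synthesis, rose in 8 of 20 cases and fell in 1 (adjusted p for the rise = 0.044), with AT4G11190 going from 5.49 ± 1.23 to 52.8 ± 6.15 FPKM. The SAUR family, which overlaps the auxin list, rose in 22 of 55 cases and fell in 9 (adjusted p for the rise = 8.6e-06). The NET group of actin-binding proteins rose in 6 of 10 cases and fell in 1 (adjusted p for the rise = 0.017), with NET4A going from 2.24 ± 0.44 to 4.61 ± 0.68 FPKM.

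Histone genes fell in 13 of 22 cases (59.1%, against 11.1% of all tested genes, Fisher exact adjusted p = 8.6e-06). In the same libraries 3 of 4 dividing-cell markers fell, a list with adjusted p = 0.28 with an estimated correlation, and the CYCB1;1 and CDKB1;1 calls were each lost without wild type 1 (limma adjusted p = 0.096 and 0.066), wild type 2 (0.12 and 0.089), hy5 4 (0.17 and 0.083) or hy5 6 (0.15 and 0.14), that of CYCB1;1 also with no filter (0.051). HTB1 went from 38.7 ± 1.0 to 23.9 ± 1.33 FPKM and AT5G59970 from 42.5 ± 2.71 to 23.7 ± 3.53 FPKM. Histone genes are near-identical, so single members are uncertain. Extensins, structural wall proteins of root hairs among other cells, fell in 7 of 11 cases (adjusted p = 0.0030) and rose in 1, with EXT13 going from 12.9 ± 3.57 to 2.54 ± 0.65 FPKM. The root and root hair markers PRP3 (log2 fold change -0.66), LRX1 (-0.68) and EXPA18 (-0.46) fell in the same libraries, while PYK10 rose. The LRX1 call was lost without hy5 4 (limma adjusted p = 0.055) or hy5 5 (0.057). Lipid transfer and albumin-type proteins fell in 14 of 50 cases and rose in 4 (adjusted p = 0.033), for example AT3G58550, from 39.8 ± 7.54 to 14.6 ± 1.44 FPKM. A homeodomain-like product class rose in 7 of 13 cases (adjusted p = 0.015), including the trihelix gene GT2. In calls dealt to genes at random, 0 families passed over 20 runs, and a planted family was found in 20 of 20. Such dealing treats genes as independent, so it does not test these p-values where family members share reads or vary together.

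The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3915 genes and the highest other split 1. For changes of at least 2-fold, the real split gave 381 and the highest other 1. Every other split mixes the genotypes, so the genotype difference enters its within-group spread and few calls are expected there. The contrast in gene counts therefore does not bear on the cause of the difference. For lists with the preset correlation, the real split gave 11 and the highest other also 11, so that 2 of 10 splits gave as many. That other split set wild type 1, wild type 3 and hy5 5 against wild type 2, hy5 4 and hy5 6 and gave 0 genes past the threshold. Like every other split, it holds unequal numbers of each genotype on its sides, so part of the genotype difference remains in its contrast. These list counts therefore do not show how many lists would pass without a genotype difference.

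Seed storage transcripts were higher in wild type and uneven among its libraries, and a second set of seed-expressed genes, written down apart from the fixed list, was lower in every hy5 library than in every wild-type library for 13 of 13 genes. This set includes SESA5 and EM6, whose falls had already been seen, so it is not independent of the pattern. The lowest relative depth of a hy5 library was 0.999, but that estimate was searched only among ratios close to equal depth. It could not have returned a much lower depth. However, the genes listed at 0 numbered 5881 to 5986 in the hy5 libraries and 5882 to 5995 in the wild-type libraries. A much lower depth would leave more genes at 0, so these counts argue against it for the hy5 libraries. Seed or embryo material in the wild-type libraries, such as late or ungerminated seeds, is a candidate explanation. The ratio of wild type 2 to wild type 1 was taken over 11 genes of the second set with at least 0.5 FPKM in wild type 1. Its median was 2.66 and all 11 ratios were above 1, while random lists of like expression had a 95th percentile of 1.12. Seed genes thus varied together between wild-type libraries, which cannot tell seed material from another shared cause. The most abundant storage genes reached 71.7 FPKM (SESA5) and 53.9 FPKM (CRA1) in wild type 2, and 4 of the 13 genes also reached 1 FPKM in every hy5 library. Of the 172 genes at least 2-fold lower, 17 had wild type 2 at 2 or more times wild type 1. Of these 17, 10 belong to the seed sets and the others, LCR67 and RAB18 among them, do not. The sets are short, so being outside them does not show that a gene is not expressed in seeds. An effect of HY5 on these genes remains open and untested.

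A set of 16 genes had at least 5 FPKM in every hy5 library and under 0.5 FPKM in every wild-type library, and all 16 passed the threshold, while 6 genes met the mirrored rule (AT1G06100, AT5G27889, LCR67, SESA1, SESA3 and SESA5). AT2G03965 stood at 292.7, 329.8 and 294.4 FPKM in hy5 4, 5 and 6 against at most 0.268 FPKM in wild type, and AT3G44265 at 129.0, 148.8 and 129.8 FPKM against at most 0.201 FPKM. A segment linked to HY5 is argued against because 0 of the 16 lie within 5 Mb of it (7 lie on chromosome 4, 4 on chromosome 2 and 0 on chromosome 5). Reads shared with a near-identical copy are argued against because 2 of 16 have another copy at 95% identity over 80% of their exons. Of these 2, AT1G27565 shares sequence at 95% identity or more with the listed gene AT1G52905, which lost 27.1% of what AT1G27565 gained. For OFP9, the listed genes that overlap such sequence had wild-type means of at most 0.802 FPKM. They were not shown to be its near-identical copy, so for OFP9 shared reads remain open. A candidate explanation is lost silencing in pseudogene-rich regions. The median number of annotated pseudogenes within 100 kb was 19.5, against 3 for the 8077 genes under 0.5 FPKM in every wild-type library. The 95th percentile of 100000 random draws was 5.5 (one-sided permutation p = 4.0e-05). Some of the 16 genes lie close together, such as OFP9 and AT4G04265, so their windows overlap, while the draws took genes independently. Location in such regions does not by itself show lost silencing. Whether HY5 itself or an unrelated difference between the seed stocks is behind the pattern was not tested.

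Clock genes of evening and dawn phase changed in opposite directions by median. The median log2 fold change was 0.45 over 7 evening-peaking genes, 6 of them above 0, and -0.23 over 11 dawn-peaking genes, 4 of them above 0, a difference of 0.68 (exact permutation p = 0.051, two-sided, across genes, which are not independent replicates). The grouping was made after these values were seen and the difference restates them, so it does not bear on whether the clock phase is later in hy5. ELF4 (-0.70) and LNK1 (0.49) went against the pattern, and its cause remains open.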
